A study of Mus musculus with 10 samples.

How the data were processed

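Droplet single-cell RNA-seq libraries (10x Genomics) of Upf2 floxed mouse neural progenitor cells infected with GFP or Cre lentivirus were analysed from the deposited tables. Per the labels' protocols, cells were collected 72 hours after infection, 1 loading and 1 cDNA are described per arm, and libraries were made with indices from the 10x plate or synthesized by IDT. The suspension volumes loaded were 23.6 µl for GFP and 33 µl for Cre. Per the submitters' processing notes, Cell Ranger 5.0.1 and the mm10 build were used. The end of the transcript that was read, the cell filters, the treatment of doublets and the method behind the stage calls are not given in the sources used here.

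The authors deposited whole-number counts per gene, summed over the cells of each of 5 cell cycle stages, with 1 column per arm in each of 2 tables, and 32285 gene rows per stage. Per the file headers, the tables also give CPM and the number of cells per stage and arm. The deposited CPM equals the count divided by the total of its stage and arm, within 5.0e-07, and was not used further. The 4 IDT libraries of an arm are pooled into 1 column of the authors' table. Samples were assigned to arms from their titles, and columns to arms from their names. The words "column labelled GFP" and "column labelled Cre" are used because several known NMD targets were lower in the latter. The analysis plan assumed CPM values, possibly per library. The tables hold counts with 1 column per arm, so the part of the plan for 1 value per arm applied, and no test, standard error or p-value was computed.

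Counts were summed over stages and divided by the column total to give CPM. The log2 fold is log2(CPM + 1) of Cre minus that of GFP within a table, which understates the difference of low genes. Genes with a mean CPM of at least 10 over both columns were kept, and a difference of at least 1 on the log2 scale was the rule of size. Folds were never taken across tables, which were scaled separately. Levels carry exact Poisson intervals, ratios exact conditional intervals, and shares of cells Wilson score intervals, with Newcombe intervals for differences of shares, all at 95% and for counting error only. Over the 92 named genes the median half-width of the Poisson interval was 3.96% to 4.87% of the level in the 4 columns, and the widest was 16.5% (Bnip3, GFP column, 10x table). Each list's median fold was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. A list counts as standing apart below the 2.5 or above the 97.5 percentile of the IDT table.

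The 28 gene lists, the comparisons of the report and the rule for named genes were fixed before the data were examined, and most tests of the closing section were chosen later. The rule takes Upf2, up to 10 genes with the highest and 10 with the lowest mean fold among those of at least 1 in size in both tables (only 8 higher ones exist), up to 4 members of each list with the largest mean fold in size, and up to 3 higher and 3 lower genes per stage. Some genes that the rule takes are not reported here. A symbol on several identifiers was taken at the identifier with the higher mean CPM. Coordinates and gene types come from GENCODE M21 (GRCm38, the assembly of mm10), which held 32158 of the 32285 identifiers. Genes of multigene families, such as the histones, and overlapping genes may share reads, as the counting settings are not given in the sources used here.

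The functions were tested on simulated data: Poisson counts at the levels of the GFP column and the depths of all columns, with 50 genes changed at each of the log2 folds 2, -2, 1.5 and -1.5. Over 7761 genes of the comparison of all stages in both tables, 100% of the changed genes of each size were recovered and 0 unchanged genes passed. The changed genes were drawn above the filter on mean CPM, their folds lay past the rule of size and the noise was Poisson only. Recovery near the filter or the rule was therefore not tested. The alternatives were other pseudocounts, filters and thresholds, centring, quantile normalization, removal of mitochondrial and ribosomal protein genes, unmatched random lists and, chosen after seeing the data, stages weighted equally, leaving out M/G1 or S, TMM scaling (edgeR 4.0.16) and median-of-ratios scaling. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used. No edgeR test was run, since 1 column per arm leaves no residual degrees of freedom.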

Results

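Single-cell RNA-seq was performed on neural progenitor cells from the cortex of C57BL/6 mice that carry floxed alleles of Upf2, a core factor of nonsense-mediated mRNA decay (NMD, the pathway that degrades transcripts with a premature stop codon). The cells were infected with a lentivirus encoding GFP or with one encoding Cre, the recombinase that cuts out floxed DNA, and were collected 72 hours later. The comparison of Cre with GFP asks what deleting Upf2 does to the progenitors, and the series title places it in a study of NMD and the tumour suppressor TRP53 in progenitor maintenance. The 10 samples form 4 groups. With a 10x Genomics plate index there was 1 library per arm, and with indices synthesized by IDT there were 4 per arm, whose values the deposited table gives as 1 column per arm. The 10x index table held 6378 cells and 26377375 counts in the column labelled GFP, and 6830 cells and 46000991 counts in the column labelled Cre. The IDT index table held 7397 cells and 35905709 counts in the GFP column, and 7080 cells and 58399919 counts in the Cre column. Mean counts per cell were 4136 and 6735 in the 10x table and 4854 and 8249 in the IDT table, so the Cre column was deeper per cell by a ratio of 1.63 and 1.70. With 1 column per arm no difference has a replicate check, and no p-value is given. Intervals are 95% and cover counting error only.

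Upf2, the targeted gene (ENSMUSG00000043241, mm10 chromosome 2, 5951469 to 6056703, plus strand), was lower in the column labelled Cre in both tables. In the 10x table its level was 31.7 CPM (counts scaled to a column total of 1000000) in the GFP column (exact Poisson interval 29.6 to 33.9) and 16.3 in the Cre column (15.2 to 17.5). In the IDT table the levels were 32.7 (30.9 to 34.7) and 16.1 (15.1 to 17.2). The log2 fold of Cre over GFP was -0.92 and -0.98. The labels do not give the deleted exons and reads from this assay cover 1 end of a transcript, so the tag may lie outside the deleted part, and this value does not settle whether the labels are right.

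The most extreme differences between the columns were in noncoding host transcripts of small nucleolar RNAs (snoRNAs) and in stress genes, several of them known targets of NMD, and these were lower in the column labelled Cre. Zfas1, a snoRNA host on chromosome 2 (167062934 to 167065862), was at 722 CPM in the GFP column (714 to 731) and 50.1 in the Cre column (48.3 to 51.9) of the IDT table, with log2 folds of -3.81 in the 10x table and -3.82 in the IDT table. Snhg15 (chromosome 11, 6525591 to 6528760) had 219 and 15.3 CPM in the IDT table and log2 folds of -3.75 in both tables. Snhg5 had log2 folds of -3.42 and -3.39, Snhg1 of -2.95 and -2.96, and Snhg12 of -2.66 and -2.65. Gadd45g, a growth arrest gene on chromosome 13 (51846678 to 51848468), was at 492 CPM (485 to 499) and 51.1 CPM (49.3 to 52.96), a log2 fold of -3.24. Of the other genes with the lowest folds, the long noncoding RNA Pvt1 had -2.75 and -2.71, and the stress transcription factor Ddit3 had -2.66 and -2.65. AY036118, a noncoding gene, had -2.82 and -2.93, and 5430416N02Rik, also noncoding, had -2.57 and -2.69. Ddit3 overlaps other annotated genes, and AY036118 and Zfas1 each overlap 1 on the opposite strand, so part of their counts may be shared with those. In the GFP column of the IDT table AY036118 was at 386 CPM in S, the stage with the fewest counts per cell, and 221 in G1/S. Whether its level follows depth was not tested.

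The genes higher in the column labelled Cre were fewer and their folds smaller. Hes5, a Notch effector that keeps progenitors undifferentiated (chromosome 4, 154960923 to 154962371), was at 69.3 CPM (66.6 to 72.1) in the GFP column and 266 CPM (262 to 271) in the Cre column of the IDT table, with log2 folds of 1.96 and 1.93. Bnip3, a mitophagy receptor induced by low oxygen, had log2 folds of 1.91 and 1.86, and the glycolytic enzyme gene Pfkl had 1.61 and 1.60. The angiogenic factor Vegfa had 1.33 and 1.19, the Wnt receptor Fzd9 had 1.35 and 1.38, and Nrarp, a feedback regulator of Notch, had 1.21 and 1.06. Mmd2 (1.12 and 1.36) and the noncoding Gm17167 (1.52 and 1.33) completed the 8 genes. By the rule of a log2 fold of at least 1 in size, 12 genes were higher and 163 lower in the Cre column among 7762 genes of the 10x table, and 12 were higher and 167 lower among 7786 genes of the IDT table. In both tables and with 1 sign, 8 were higher and 147 lower among 7691 genes. Of the genes lower in both, 20 were among the 117 tested genes that are not protein-coding (17.1%) and 127 were among the 7571 protein-coding genes (1.68%).

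**Figure D1:**
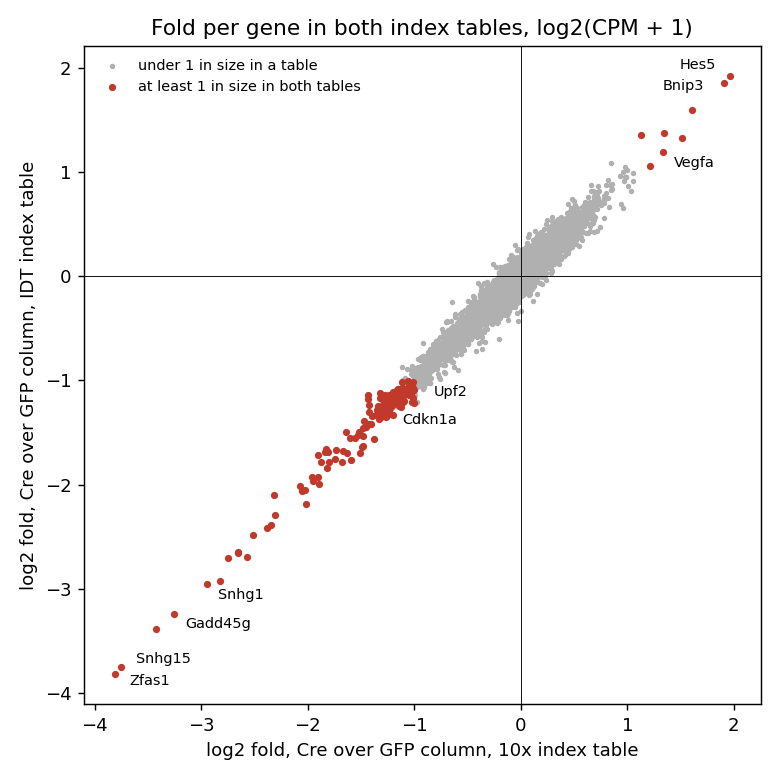
Each point is a gene, with its log2 fold of the column labelled Cre over the column labelled GFP in the 10x index table (horizontal axis) and in the IDT index table (vertical axis); red marks the 155 genes of at least 1 in size in both. Zfas1 lies lowest at -3.81 and -3.82, and Hes5 highest at 1.96 and 1.93.

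**Figure D2:**
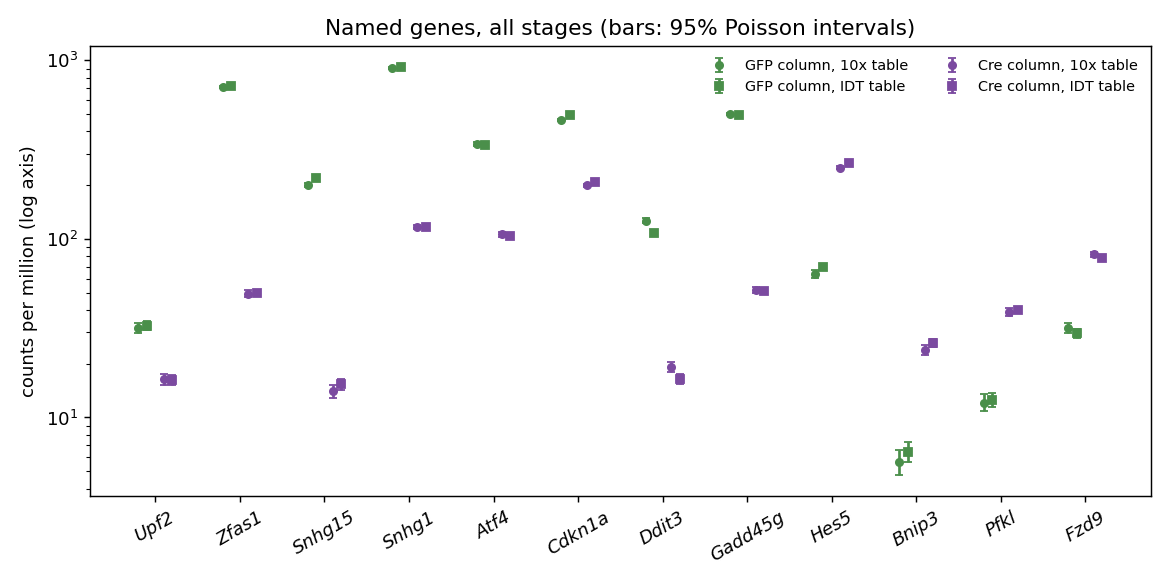
CPM over all stages (vertical log axis) of 12 named genes in the GFP column (green) and the Cre column (purple); circles are the 10x index table, squares the IDT index table, and bars are 95% Poisson intervals. Upf2 was at 32.7 and 16.1 CPM and Hes5 at 69.3 and 266 CPM in the IDT table.

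Among the gene lists tied to the targeted pathway, snoRNA host genes stood farthest from random lists. Of their 14 measured members, 8 were lower in the Cre column by at least 1 on the log2 scale in both tables and 0 were higher, and the median log2 fold was -1.45 in the 10x table and -1.54 in the IDT table, below all 10000 matched random lists in both. Transcripts known to be sensitive to NMD had 13 of 46 members lower and 0 higher, with medians of -0.19 and -0.23, also at percentile 0. This list holds most of the snoRNA hosts, so it is not independent of the first. The NMD factors had medians of -0.29 (percentile 0.08) and -0.25 (percentile 0.26) over 20 members, with Upf1 at -0.95 and -0.93 and the kinase gene Smg1 at -0.94 and -0.80. With genes of at least 50 CPM alone, the NMD factor median was -0.065, at percentile 21.1. The SR and hnRNP splicing factors did not stand apart (medians -0.021 and 0.022, percentiles 27.5 and 52.0), although Tra2b was at -1.17 and -1.19, Srsf10 at -0.57 and -0.52, Ptbp1 at -0.44 and -0.50 and the kinase gene Clk4 at -0.45 and -0.47.

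Targets of p53, the protein encoded by Trp53, were lower in the column labelled Cre. Of 27 measured targets 25 had a fold below 0 in both tables, 8 of them by at least 1, and the medians were -0.74 and -0.77, both at percentile 0. The cell cycle inhibitor gene Cdkn1a was at 492 CPM (485 to 500) in the GFP column and 207 CPM (204 to 211) in the Cre column of the IDT table, log2 folds of -1.21 and -1.24. Phlda3, which restrains AKT signalling, had -1.48 and -1.45, Dcxr had -1.44 and -1.42, and the stress gene Sesn2 had -1.52 and -1.49. The integrated stress response list had 22 of 23 members below 0 and 6 by at least 1, with medians of -0.50 and -0.45 at percentile 0. The stress list shares Sesn2 with the p53 targets and Atf4, Ddit3 and Atf3 with the NMD-sensitive transcripts, so it is not independent of those lists. Its transcription factor gene Atf4 was at 335 CPM (329 to 341) and 104 CPM (102 to 107), a log2 fold of -1.67 in both tables, and Nupr1 was at -1.95 and -1.97. Apoptosis genes had a median of -0.20 at percentile 1.93 in the IDT table and -0.15 at percentile 11.9 in the 10x table, so the list did not keep its place in both. Bbc3, a p53 target that promotes cell death, had -1.01 and -1.09, and Bax -0.56 and -0.57, while Mcl1 and Bcl2l1, which oppose cell death, had -0.84 and -0.47 in the IDT table. The unfolded protein response list was within random lists (medians -0.086 and -0.072, percentiles 16.9 and 18.2), with Hyou1 at -0.64, Herpud1 at -0.56, Xbp1 at -0.38 and the chaperone gene Hspa5 at -0.19 in the IDT table.

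Cell cycle and progenitor genes lay on the higher side in the column labelled Cre. The G2 and M phase list had medians of 0.38 and 0.40, above all random lists, with 49 of 54 members above 0 in both tables and 0 reaching 1. The Cre column also held larger shares of G2 and G2/M cells, and within stages the median was smaller, from 0.070 to 0.36, and past the upper limit in 9 of 10 combinations of stage and table. The proliferation marker Mki67 was at 216 CPM (211 to 221) and 378 CPM (373 to 383), log2 fold 0.80 (0.49 to 0.91 within stages), and Cdca2, Ccnb2 and Cks2 had 0.88, 0.74 and 0.71 in the IDT table. The S phase list had medians of 0.17 and 0.18 at percentile 100, 29 of 41 members above 0 and 10 below in both tables, with the histone chaperone gene Nasp at 0.60, the replication helicase gene Mcm5 at 0.52 and Gmnn at 0.50. Without the stage M/G1 its median was 0.021, at percentile 81.1. Histone genes had medians of 0.33 and 0.31, 11 of 14 members above 0 and 3 below, with Hist1h1b at 1.00 and 1.02, Hist1h2ap at 0.96 and 0.66, H2afv at 0.62 and 0.61 and Hist1h1a at 0.63 and 0.56. The G1 and cell cycle exit list had members on both sides (percentiles 35.1 and 51.6), among them Gadd45g, Cdkn1a, cyclin D1 (Ccnd1, 1496 and 827 CPM, log2 fold -0.85) and the antiproliferative gene Btg2 (0.69 and 0.70). Radial glia and neural stem cell markers had medians of 0.29 and 0.24 at percentiles 100 and 99.98, 12 of 17 members above 0 and 5 below, led by Hes5, Nr2e1 (0.66 and 0.88), Pax6 (0.43 and 0.48) and Sox2 (0.45 in both). The DNA repair list was at 0.12 in both tables, at percentiles 98.5 and 97.52, with Brca2 at 0.57, Atr at 0.52 and Mdc1 at 0.45 in the IDT table, and it lost its place under 9 of 14 other settings. Notch and Wnt genes were within random lists (percentiles 91.3 and 77.0), although Lfng was at 0.60 and 0.59, Notch1 at 0.44 and 0.43 and Dll1 at 0.38 and 0.30.

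Markers on the lists for other neural cell types passed the filter in part: 10 of 22 for neurons, 9 of 14 for astrocytes and 4 of 12 for the oligodendrocyte lineage. Some were abundant, such as Gap43 (600 CPM) and Olig1 (1006 CPM) in the GFP column of the IDT table. Neuron markers had a median of -0.24 at percentile 2.53 in the 10x table and -0.32 at percentile 0.37 in the IDT table, with the synaptic gene Syt1 at -1.83 and -1.66, Stmn4 at -1.25 and -1.28, Gap43 at -0.78 and -0.83 and Mapt at -0.57 and -0.50. Intermediate progenitor markers had 5 measured members and were within random lists (percentiles 68.5 and 60.7), with Gadd45g low, Hes6 at -0.27 and -0.25 and Igsf8 at 0.46 and 0.47. Astrocyte markers (percentiles 25.9 and 25.8) held Sparcl1 at -0.76 and -0.77 and Clu at -0.98 and -1.01 beside Aldoc at 0.75 and 0.70 and Slc1a2 at 0.53 and 0.60. Oligodendrocyte lineage markers (percentiles 14.7 and 20.7) held Olig2 at -0.35 and -0.37, Cspg4 at -0.23 and -0.14, Olig1 at -0.06 in both and Cnp at 0.14 and 0.13. The interferon list rested on 4 measured genes, with medians of -0.63 and -0.58 (percentiles 0.53 and 0.74), among them Ifi27 at -2.31 and -2.30, B2m at -0.46 and -0.43 and H2-K1 at 0.47 and 0.44. Immediate early genes were within random lists (percentiles 90.9 and 79.4), with Ier2 at -1.03 and -1.12, Fos at -0.51 and -0.47 and Egr1 at 0.36 and 0.39. No marker of microglia, endothelium, mesenchyme, erythroid cells or interneurons passed the filter on mean CPM, and the highest levels reached by a member of these lists were 1.29, 1.18, 4.01, 0.39 and 10.3 CPM. Mitochondrially encoded transcripts took 3.74% and 3.96% of counts in the GFP and Cre columns of the 10x table and 4.33% and 4.38% in the IDT table. Their list median was -0.063 at percentile 7.48 and -0.20 at percentile 0.23, with mt-Nd4l at -0.63 and -0.82, mt-Atp8 at -0.42 and -0.72, mt-Nd6 at -0.36 and -0.69 and mt-Nd5 at -0.55 and -0.49. Ribosomal protein genes had 33 of 36 members above 0 and 1 below in both tables. They were within matched random lists (percentiles 96.3 and 91.8), but at percentile 99.2 of unmatched ones in the IDT table. Among them Rplp0 was at 0.37 and 0.35, Rps23 at 0.39 and 0.31, Rpl3 at 0.33 and 0.31 and Rpl4 at 0.35 and 0.28.

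**Figure D3:**
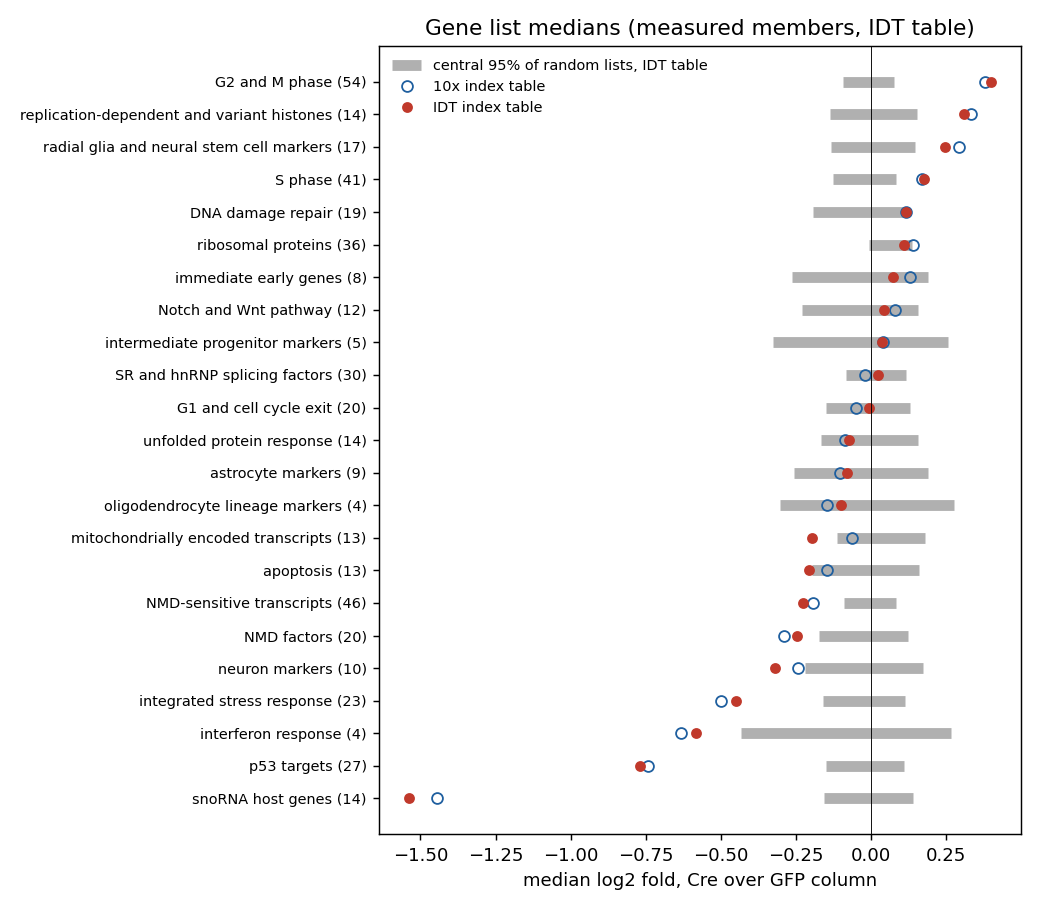
Median log2 fold of Cre over GFP (horizontal axis) of the 23 gene lists with measured members (number measured in the IDT table in parentheses); filled points are the IDT index table, open points the 10x index table, and grey bars the central 95% of 10000 matched random lists. The snoRNA hosts lie at -1.54 and the G2 and M phase genes at 0.40 in the IDT table.

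The folds of the index tables were then set side by side to see how far the library step repeats. Zfas1, at -3.81 and -3.82, and Hes5, at 1.96 and 1.93, had nearly equal folds in both. Across 7691 genes Pearson's r was 0.976 and Spearman's rho 0.959, and the SD of the difference of folds was 0.081; genes are not independent replicates. Of the genes past the rule in the IDT table and tested in both, 177 of 177 had the same sign in the 10x table. Abundant genes differed between the tables by more than sampling noise, but the tables also differ in the cells they hold, so this does not show separate libraries. The protocol describes 1 cDNA per arm, so this agreement concerns the libraries and not separate cultures.

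The cell cycle stages the authors gave to the cells were compared between the columns. S and M/G1 held a smaller share of cells in the column labelled Cre, and G1/S, G2 and G2/M a larger one. In the 10x table S held 27.2% of cells in the GFP column (26.1 to 28.3) and 20.97% in the Cre column (20.0 to 21.9), and M/G1 held 25.7% (24.6 to 26.8) and 17.9% (17.0 to 18.8). G2 held 13.1% and 18.0%, G2/M 14.8% and 20.8%, and G1/S 19.2% and 22.3%. In the IDT table S held 32.3% (31.2 to 33.3) and 22.6% (21.7 to 23.6), M/G1 22.8% and 17.4%, G2 13.2% and 19.6%, G2/M 14.2% and 19.1%, and G1/S 17.5% and 21.2%. Newcombe intervals of these differences, which treat cells as independent, excluded 0. The same intervals also excluded 0 in 6 of 10 differences between the tables of 1 arm, up to 5.11 points (S, GFP column), so they do not cover the difference between libraries. In each stage both differences between the arms had 1 sign and were larger in size than those between the tables, most narrowly in S (-6.19 and -9.66 points against 5.11 and 1.65). No replicate culture checks them. The S cells of the GFP column were also the shallowest, with 3094 and 3254 mean counts per cell against 6334 and 7605 in the Cre column. The method that called the stages is not given in the sources used here, so an effect of this depth gap on the shares was not excluded.

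**Figure D4:**
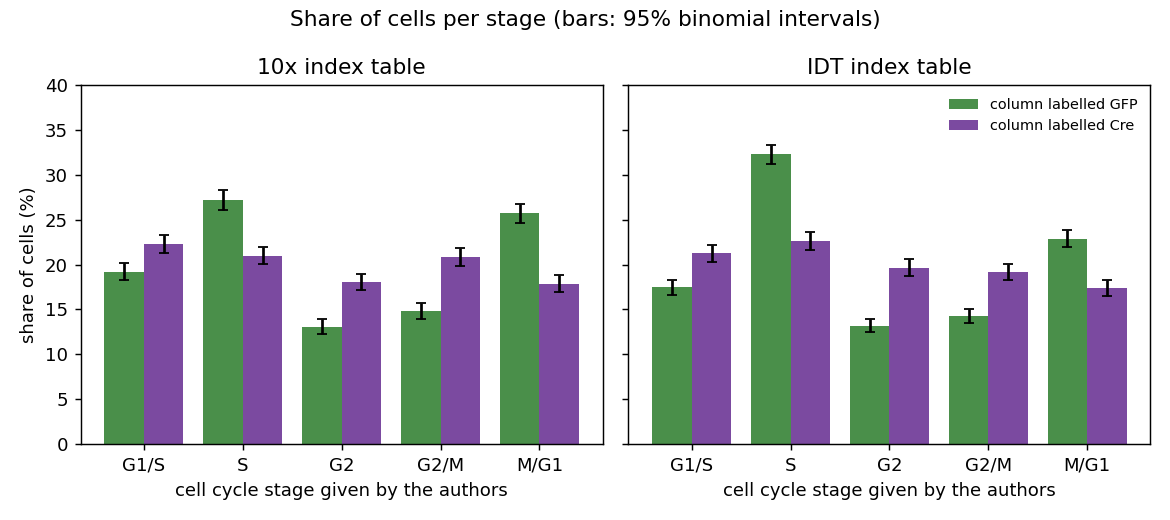
Share of cells (vertical axis, percent) in each of the 5 stages given by the authors (horizontal axis) in the GFP column (green) and the Cre column (purple) of each index table, with 95% Wilson intervals. S is 32.3% in the GFP column and 22.6% in the Cre column of the IDT table, and G2 is 13.2% and 19.6%.

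The columns were also compared within each stage, where a snoRNA host again lay lowest and Hes5 was among the highest. Zfas1 and Snhg15 were among the 3 lowest genes in each of the 5 stages, with Zfas1 between -3.98 (G1/S, 10x table) and -3.61 (G2/M, 10x table), and Hes5 was among the 3 highest in each, between 1.52 (S, IDT table) and 2.27 (M/G1, IDT table). Fzd9 was among the 3 highest in G1/S (1.51 and 1.44) and S (1.51 and 1.54), and Bnip3 in G2 (2.41 and 2.13), G2/M (2.26 and 2.27) and M/G1 (2.34 and 2.44). Selenbp1, a selenium-binding protein gene, led M/G1 at 2.91 and 2.54, from 2.33 to 18.4 CPM in the IDT table. Genes past the rule in both tables, higher and lower, numbered 7 and 136 in G1/S, 6 and 122 in S, 11 and 113 in G2, 14 and 125 in G2/M, and 23 and 186 in M/G1. All 155 genes past the rule over all stages had 1 sign in all 10 combinations of stage and table, and 85 of them were at least 1 in size in all 10. These genes were chosen on the sums of the same stages, so this agreement is partly built in. The snoRNA host median lay between -1.61 and -1.28, the p53 target median between -0.91 and -0.54 and the radial glia median between 0.19 and 0.38 over these combinations. Other lists kept their place in fewer of the 10. S phase, interferon and neuron markers (highest median -0.019, percentile 46.4) each did so in 7. The S phase median was lowest in G1/S, at 0.038 (percentile 93.0) in the 10x table and 0.039 (percentile 88.0) in the IDT table. Histones (lowest 0.087, percentile 86.6) and DNA repair kept theirs in 5, mitochondrially encoded transcripts in 4 and apoptosis in 0. Some lists that were within random lists over all stages stood apart in 1 stage of both tables. The unfolded protein response did so in G1/S (percentiles 1.80 and 0.21) and ribosomal proteins in M/G1 (98.9 and 98.1). SR and hnRNP factors did so in G2 (1.53 and 0.98) and were also low in G2/M of the 10x table (1.07). Cdkn1a was highest in M/G1 of the GFP column, at 675 CPM in the IDT table against 366 to 443 in its other stages, and was 179 to 225 in the stages of the Cre column. Its log2 ratio of Cre over GFP in M/G1 minus that in the other stages together was -0.60 in both tables, with 95% counting half-widths of 0.093 and 0.081 and no replicate check. Other named genes lower in the Cre column went either way in this difference, such as Gadd45g (-0.47 and -0.46) and Nupr1 (0.96 and 0.98).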

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

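No paired analysis was possible because the tables hold 1 column per arm and no result comes from a test. For the same reason the planned fits without each IDT replicate, with the replicate number as a block, over all 10 libraries, and with camera or fry were not run. Settings that weight stages equally, leave out a stage, or use TMM or median-of-ratios scaling were chosen after seeing the data. Of 39 counts of genes 27 stayed within 1.5 times, as did 24 of 42 counts within stages, and 295 of 319 list medians kept their side of the percentile limits. The lists of snoRNA hosts, p53 targets, NMD-sensitive transcripts, stress response, G2 and M phase, radial glia and histones kept theirs under all settings run, with the G2 and M phase median between 0.20 and 0.47. The counts moved further with another filter, a lower threshold or a pseudocount of 5. Depth limits genes under 10 CPM, which the main filter leaves out.

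In the IDT table, the 10x table and both, the counts were 112, 113 and 100 with a pseudocount of 5, 302, 298 and 251 with no filter on mean CPM, 51, 49 and 45 with a mean CPM of at least 50, and 679, 694 and 588 with a log2 fold of at least 0.58, where 95 of the 588 were higher and 493 lower, a less uneven split than the 8 and 147 of the main rule. Without the filter r between tables was 0.919. Within stages, a pseudocount of 5 gave 88 in G1/S, 91 in G2/M and 125 in M/G1. In the order G1/S, S, G2, G2/M and M/G1, no filter gave 227, 217, 207, 226 and 339, at least 50 CPM gave 44, 40, 36, 43 and 62, and a log2 fold of at least 0.58 gave 492, 495, 472, 493 and 745.

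Some list medians crossed a percentile limit, and the cause was not tested. With at least 50 CPM the NMD factors were at -0.065, apoptosis at -0.20, neuron markers at -0.17, DNA repair at 0.15 and Notch and Wnt genes at 0.43. Without M/G1 the S phase list was at 0.021, apoptosis at -0.14 and DNA repair at 0.031. With unmatched random lists apoptosis (-0.20), mitochondrially encoded transcripts (-0.20), DNA repair (0.12) and ribosomal proteins (0.11) crossed. In the 10x table apoptosis was at -0.15, neuron markers at -0.24 and mitochondrially encoded transcripts at -0.063. Apoptosis was at -0.14 without mitochondrial and ribosomal protein genes, -0.18 with stages weighted equally and -0.13 with median-of-ratios scaling. DNA repair was at 0.090 with a pseudocount of 5, 0.17 with quantile normalization, 0.016 with stages weighted equally, 0.10 without S, 0.18 with TMM and 0.18 with median-of-ratios scaling. Of 1145 folds of named genes 935 stayed within counting error, 143 moved nearer to 0, 65 moved away and 2 turned. Of the named genes 33 were at least 1 in size in the IDT table, and 6 of them fell under it in some setting: Vegfa (0.86) and Stmn4 (-0.97) with a pseudocount of 5, and Nrarp (lowest 0.88), Hist1h1b (0.81), Clu (-0.78) and Bbc3 (-0.90) in several. Olig1 turned from -0.06 to 0.0080 with TMM and 0.012 with median-of-ratios scaling.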

Other observations

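The 2 set tests of exchanged columns, the tests of stage mix and scaling for the NMD pattern and both tests of the S share were chosen after the results they bear on had been seen, in part for the set tests. The tests of the oxygen and glycolysis set were written before its members were looked at.

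A group of genes regulated by oxygen or belonging to glycolysis was higher in the column labelled Cre. It was listed after Bnip3, Vegfa, Pfkl, Ddit4 and Aldoc had been seen, and those genes were left out of it. Of 23 measured members 21 were above 0 in both tables and 0 reached 1, with medians of 0.44 in the 10x table and 0.42 in the IDT table, above all matched random lists. The oxygen sensor gene Egln3 was at 0.93 and 0.97, lactate dehydrogenase A (Ldha) at 0.78 and 0.74, Egln1 at 0.69 and 0.72 and phosphoglycerate kinase (Pgk1) at 0.45 and 0.50, while Adm was at -0.32 and -0.47 and Pfkp at -0.70 and -0.64. The lower median of the tables, 0.42, is what a set that moves together would show. A different mix of cell cycle stages is argued against, since the lowest of the 10 medians within stages was 0.30. A difference in oxygen or density between the cultures may underlie the pattern and was not tested, as the protocol describes 1 loading per arm and does not say how many wells went into it.

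In the column labelled Cre, the arm in which the design deletes an NMD factor, 13 of 46 measured NMD-sensitive transcripts were lower by at least 1 and 0 higher, while 11 were above 0 in both tables, such as Snhg3 (0.28 in both) and Hnrnpl (0.22 and 0.21). A different mix of stages is argued against, since the snoRNA host median was -1.28 or lower in each stage and table, and so is scaling by a few abundant genes, since the list lay -1.41 from the median of all tested genes in the table where the gap was smaller. An exchange of the GFP and Cre columns may explain the direction, and the 2 set tests did not decide it. The NMD factor list, fixed in advance, holds several transcripts known to rise when the pathway is inhibited. It was low (percentiles 0.08 and 0.26), with 13 of 20 members below 0 and 6 above in both tables. With at least 50 CPM its percentile was 21.1. It includes Upf2 and shares members with the NMD-sensitive transcripts. The SR and hnRNP factors, also fixed in advance, did not stand apart (percentiles 27.5 and 52.0). Annotated snoRNA hosts outside the fixed list were at percentile 85.7 in the IDT table, the one the test names, and 97.6 in the 10x table. Neither value met the prediction for an exchange, and only the latter was as high as the opposite needs. Of the 194 measured hosts 187 are protein-coding, unlike the noncoding hosts that were lowest. Whether such hosts respond to NMD was not tested, so this set counts neither for nor against an exchange. Genes with an annotated NMD transcript were at percentile 0.12 in the IDT table, as an exchange predicts, but by a median of only -0.048. Upf2 (-0.92 and -0.98) was lower in the Cre column, as was the untargeted Upf1 (-0.95 and -0.93), so Upf2 decides neither way. An exchange therefore cannot be told apart from a true difference of the Cre arm, because no count of a viral sequence or of the deleted exons is in the tables used, and no value here reassigns a column.

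In the column labelled GFP the share of S cells was higher in the IDT table than in the 10x table, although the protocol describes 1 cDNA per arm. The difference was 5.11 points (3.59 to 6.64), which counting error of cells does not cover, and the intervals of M/G1 (-2.85) and G1/S (-1.77) in the GFP column and of S (1.65), G2 (1.61) and G2/M (-1.70) in the Cre column excluded 0 too. Added shallow cells called S in the IDT table may contribute, since mean counts per cell of the IDT table over the 10x table had a ratio of 1.05 in S against 1.14 to 1.29 in the other stages, and 655 of the 1019 added cells were S. No biological explanation was tested, because both tables come from the same arm.

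The 7 measured snoRNA hosts outside the fixed list that the annotation does not type as protein-coding, named after their values were seen, did not stand apart as a set, with medians of 0.015 and 0.0039 at percentiles 51.5 and 44.5. Of these, 2410006H16Rik (-2.05 and -2.06), Snhg16 (-1.68 and -1.78) and 1110038B12Rik (-1.46 and -1.45) were lower in the Cre column. The others were Dancr (0.44 and 0.46), 2700038G22Rik (0.41 and 0.21), AI506816 (0.080 and 0.10) and Cct6a (0.015 and 0.0039), a chaperonin subunit gene that the annotation types as a processed transcript.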
